A study of Danio rerio with 6 samples.

How the data were processed

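RNA was measured in 6 libraries of mpeg1-GFP positive brain cells of adult zebrafish, 2 each of wild-type control, csf1ra-/- and csf1ra-/-;b+/- (compound mutants). Per the sample labels, brains were dissociated with trypsin, the cells were enriched on Percoll and sorted for GFP, cDNA was made with a low-input kit, and single reads were sequenced. Ages were given as 9 to 12 months and the strain as TLF x AB for all samples. The submitters' processing notes name HISAT2, edgeR and the GRCz10 assembly, and versions, annotation and counting settings are not given in the sources used here. The labels name no batches. A description of the compound mutants reads as loss of both receptors while their genotype gives 1 mutant csf1rb copy, and the genotype was followed. The series' design text describes samples other than these 6, and was not used.

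The authors deposited 1 table of 21860 genes. Its signal values, headed CPM, are reads divided by an effective library size, per the file headers and the values, since 3 of the columns sum to more than a count per library scaled to its total would allow. Every value was a whole multiple of the smallest value of its library within a tolerance of 0.001, so whole reads could be recovered. The log2 fold changes in the table are the authors' own, between groups, and so are the FDR values given as p-value columns of the same 4 comparisons, as deposited. Another 22 columns were not used. Every gene had at least 1 read per 1e6 total reads in 2 or more libraries, so genes with few reads had been left out before deposition. Effective size over total reads was 1.73 and 1.03 in the controls, 1.07 and 0.810 in csf1ra-/-, and 0.823 and 0.802 in compound mutants. The file gives no coordinates. No reference genome sequence was used, and the GRCz12tu annotation was used for a test of neighbouring genes.

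Before the data were examined, an edgeR quasi-likelihood test on counts was planned, with the groups, the comparisons, the gene lists, the rule for named genes and a set of alternatives. Because the deposited values are normalized rather than counts, the test used here is limma with an intensity trend on log2 of signal plus 1, for 21316 genes with a signal of at least 1 in at least 2 libraries. The planned edgeR test was run on the recovered reads and is reported as an alternative. All 6 libraries were fitted with 3 group means and no covariate, and p-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Comparisons were csf1ra-/- against control, compound mutants against control, compound mutants against csf1ra-/-, and the mean of both mutant groups against control. Standard errors are those of the moderated fit and SD is between the 2 libraries of a group. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

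There were 24 gene lists, namely CSF1 receptors and their ligands, microglia and macrophage identity, lysosomal proteins, chemokines and chemoattractant receptors, integrins and leukocyte cytoskeleton, antigen presentation, interferon response, inflammatory mediators, cholesterol and lipid handling, cell proliferation, growth factors and iron, immediate early and heat shock genes, ribosomal proteins, respiratory chain subunits and the mitochondrial genome. Markers of other cells made up lists for neutrophils, B lymphocytes, T and natural killer cells, epithelium and metaphocytes, neurons, radial glia, oligodendrocytes, vessels, and red cells and thrombocytes. Symbols absent from the table, csf1a among them, have no value. Lists with at least 5 tested members, 23 of them, were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Members that passed were counted over all genes and also adjusted over the list alone.

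Named genes were the receptors and ligands, up to 10 rises and 10 falls with the largest fold change among genes that passed, did not overlap between groups, had a mean of at least 20 reads in the higher group and carried a gene symbol that was not clone-style, and up to 4 members with the smallest p of each list. Folds against groups at 0 reads used a floor of 3 reads over the group. Other settings fixed in advance were DESeq2, median-ratio scaling, no filter, at least 50 reads in 2 libraries, the title number as a block, each library left out, a fit without robust estimation, only the 4 libraries compared, mutant libraries pooled, an estimated correlation and fry. Chosen after seeing the data were limma as the main test, pseudocounts of 0.25 and 4, and scaling to total reads. The planned edgeR test then became an alternative. For the list results, median-ratio scaling was also chosen after seeing the data. Shared controls were simulated 100 times for limma and 10 times for edgeR with a seed of 1.

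The tests were tested on simulated data with the sizes of these libraries, with genes changed 4-fold, 16-fold or 64-fold. For compound mutants against control limma recovered 5 of 34 genes raised 4-fold, 31 of 33 raised 16-fold and 33 of 33 raised 64-fold, and 3 of 33, 17 of 34 and 22 of 33 lowered. It made 117 calls, 6 of them false, against 106 and 0 for edgeR and 291 and 153 for DESeq2. With no change simulated limma called 0 of 20125 genes. A list of 40 genes raised 3-fold had a camera adjusted p of 1.37e-26, and 0 of 20 random lists were called. Simulated genes were drawn independently, while estimated correlations within the real lists reached 0.950. The simulation thus cannot show how often camera falsely calls lists of correlated genes.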

Results

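Brain cells carrying the mpeg1-GFP reporter, which marks macrophages including microglia in zebrafish, were sorted by flow cytometry from fish 9 to 12 months old, and their RNA was amplified and sequenced. The 6 libraries fall into 3 groups of 2. The control fish were wild type, the csf1ra-/- fish were homozygous csf1ra mutants by genotype, and the csf1ra-/-;b+/- fish, called compound mutants from here on, also carried 1 mutant copy of csf1rb. These genes are the zebrafish pair of receptors for colony-stimulating factor 1 and interleukin 34, signals on which macrophages depend. The series title sets control microglia against csf1r mutant microglia, and the comparisons below ask how each mutant group differed from control and from the other. The labels do not say that the libraries of a group came from separate fish or pools, so the p-values measure only the spread between these samples, which may be technical.

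Reads over the 21860 genes of the table came to 4241988 and 7830510 in the control libraries, 8028386 and 7874979 in the csf1ra-/- libraries, and 15011963 and 13543998 in the compound mutant libraries. The control and compound mutant groups thus differ most in depth, and 1 read was worth from 0.0809 to 0.157 units of signal. Signal, CPM in the file headers, is the number of reads over the library size as the authors scaled it, and values below are in these units. Between libraries, Spearman's correlation across genes ranged from 0.536 to 0.827. The compound mutant replicates correlated at 0.827, the csf1ra-/- replicates at 0.731 and the control replicates at 0.672, and genes are not independent replicates in such a value. Some pairs from different groups lay higher. Control replicate 2 and csf1ra-/- replicate 1 correlated at 0.703, and csf1ra-/- replicate 1 and compound mutant replicate 1 at 0.747. Only the compound mutant replicates correlated more with each other than either did with any other library. More genes had at least 1 read in the control libraries (21452 and 20723) than in the compound mutant libraries (18383 and 18047), although the latter were sequenced more deeply. The csf1ra-/- libraries held 20971 and 20119 such genes.

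**Figure D1:**
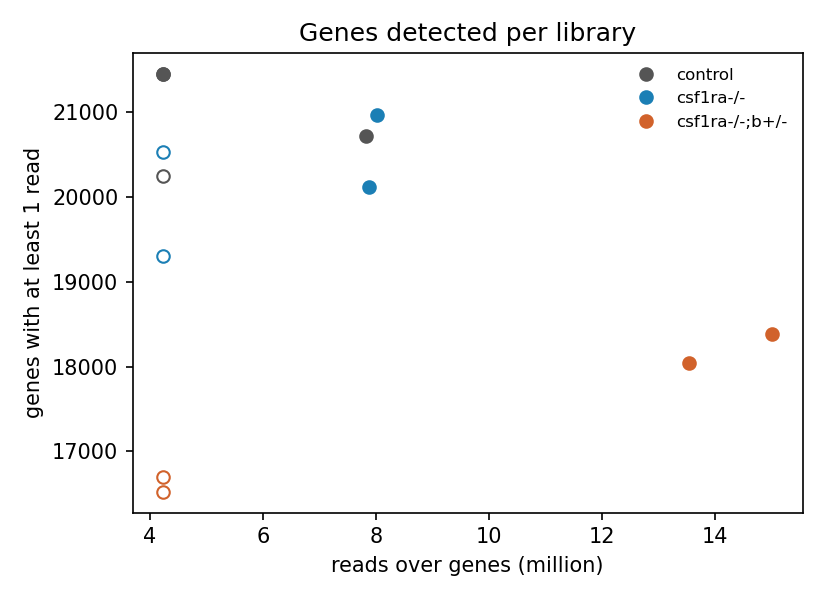
Genes with at least 1 read against the sum of reads over genes, for the 6 libraries, colored by group. Filled circles are the libraries as deposited and open circles the same libraries thinned to 4241988 reads, at which the compound mutant libraries held 16702 and 16524 genes and the controls 21452 and 20242.

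The targeted receptors were read first. Transcripts of csf1ra (ENSDARG00000102986) were present in every library, at 37.7 and 67.9 units of signal in control, 42.6 and 24.3 in csf1ra-/-, and 18.5 and 7.73 in compound mutants. Transcripts of csf1rb (ENSDARG00000053624) stood at 901 and 1356 in control, 1432 and 783 in csf1ra-/-, and 329 and 173 in compound mutants. A value per gene counts reads from any allele, so neither receptor checks the genotype of a library. In compound mutants against control the log2 difference was -2.21 ± 0.56 (SE, n = 2 per group) for csf1rb and -1.98 ± 0.68 for csf1ra, with limma adjusted p of 0.0725 and 0.107. The ligand gene il34 (ENSDARG00000091003) stood at 54.6 ± 2.48 (SD, n = 2) in compound mutants against 8.36 ± 9.13 in control and 5.85 ± 4.81 in csf1ra-/-, a log2 difference of 3.04 ± 0.93 from control with an adjusted p of 0.0929. That difference ran from 1.81 to 4.26 with 1 library left out, as the controls stood at 1.90 and 14.8. Adjusted over the list alone, these 3 of the 4 measured receptor and ligand genes passed, 1 higher and 2 lower, at 0.0102, 0.0201 and 0.0169 in the order given. In csf1ra-/- against control the log2 differences were -0.64 for csf1ra, -0.06 for csf1rb and -0.19 for il34, and none of the 4 genes passed either adjustment. Against csf1ra-/-, csf1rb differed in compound mutants by -2.14 and il34 by 3.22, with limma adjusted p of 0.248 and 0.269 over all genes and 0.0120 for both adjusted over the list alone. In the mean of both mutant groups against control, the log2 differences were -1.13 for csf1rb, -1.31 for csf1ra and 1.42 for il34, and none passed either adjustment. In the authors' deposited table, csf1rb was lower in compound mutants than in control by a log2 fold change of -2.17 (false discovery rate 0.0113). There il34 was higher by 2.70 (0.0450), while csf1ra, at -2.01, did not pass 0.05 (0.0511). The other ligand measured, csf1b, was near the detection limit at 0.741 in control, 0.921 in csf1ra-/- and 0.243 in compound mutants.

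**Figure D2:**
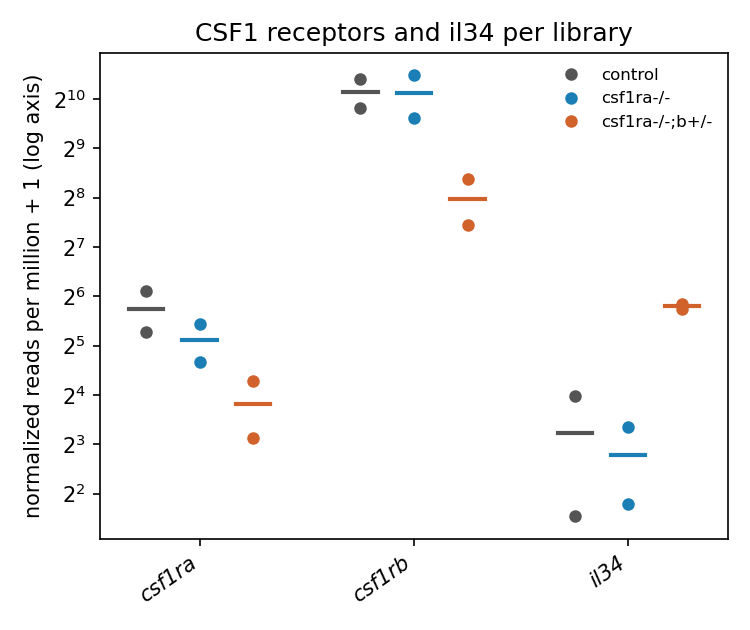
Signal (normalized CPM) plus 1 on a log axis for csf1ra, csf1rb and il34 in each library, with circles for libraries, a short line for the mean of a group, and colors for the groups. The compound mutant libraries lie below all others for both receptors and above all others for il34, at 52.8 and 56.4.

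In csf1ra-/- against control, no single gene passed the test, while camera called 7 of 23 tested gene groups as above other genes. With an estimated correlation among members 0 were called, and each of the 7 was at adjusted p = 0.692. The chemokine list was among the 7 although its estimated correlation, -0.0156, lay below the preset 0.01. Its loss thus does not come from correlation among members. With 3 group means fitted to 6 libraries, that setting also has few degrees of freedom. A call lost in it therefore does not show that the members of a list are correlated. Cytosolic ribosomal proteins were higher in 76 of 78 tested members, with a median log2 difference of 1.24, such as rpl35 at 1338 against 492 units of signal. Nuclear-encoded subunits of the respiratory chain were higher in 77 of 82 members, with a median of 0.73. Among them were cox7a1 (3.48 ± 0.67 SE, n = 2 per group) and cox8b (2.93 ± 0.66). The camera test gave adjusted p of 4.08e-23 for the ribosomal and 1.56e-09 for the respiratory group. With an estimated correlation both were at adjusted p = 0.692. On total reads the median of all genes moved from -0.03 to -0.45, and relative to it the ribosomal median was 1.16 and the respiratory median 0.70. The other groups above the threshold were chemokines and chemoattractant receptors (median 0.44, adjusted p = 0.0109), and B lymphocyte markers (0.59, adjusted p = 0.0135). With an estimated correlation these 2 were at adjusted p = 0.692. Also above it were antigen presentation (0.51, adjusted p = 0.0201), immediate early and heat shock genes (0.59, adjusted p = 0.0182) and genes of the mitochondrial genome (0.70, adjusted p = 0.00923). These 3 were at adjusted p = 0.692 with an estimated correlation too, and all camera p-values are adjusted over the lists. The immediate early call ended on total reads (0.0586) and without control replicate 1 (0.275), and its direction turned without csf1ra-/- replicate 1 (0.953). Camera called 1 list without control replicate 1 (the respiratory group was at 0.333) and 3 without csf1ra-/- replicate 1. The ribosomal group alone was called in each of 11 alternative settings, which leave out the estimated correlation (0 lists called) and fry (1 called).

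By limma, 0 genes passed in csf1ra-/- against control at an adjusted p under 0.05, 2242 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0521. On the recovered reads, edgeR called 8 genes, 5 higher and 3 lower, and DESeq2 called 264. The authors' deposited table holds 164 genes under a false discovery rate of 0.05, 135 higher and 29 lower. The 8 genes of edgeR were all among them. They include epdl1, an ependymin-related secreted protein, at 474 ± 70.0 (SD, n = 2) in csf1ra-/- against 31.6 ± 5.44 in control (edgeR adjusted p = 0.0268). Also among them was sftpba, of the surfactant protein B family, at 212 ± 112 against 7.93 ± 2.94 (edgeR adjusted p = 0.0263). The transcripts CU929449.2, zgc:171695 and si:dkey-18p12.4 had 0 reads in both csf1ra-/- libraries and 220 ± 118, 160 ± 50.5 and 107 ± 39.5 units of signal in control. The remaining edgeR calls, all higher, were si:dkey-286j15.3, si:ch211-226m16.2 and si:dkey-5n18.1. All 8 were named after their values were seen, and in limma their adjusted p ranged from 0.0521 to 0.123.

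Adjusted over the list alone, limma passed a few members in csf1ra-/- against control. These were 3 chemokine genes higher (ccl34b.8, ccl33.3 and ccl35.2), and 3 B lymphocyte markers higher (ighv1-4, ighz and CD37). There were also 3 T and natural killer markers higher and 2 lower, 2 epithelial markers higher, 2 respiratory subunits higher, and 1 each higher of the interferon list (tlr3) and the oligodendrocyte list (tspan2a). In the remaining lists 0 members passed this adjustment. Over all genes 0 list members passed, and ccl34b.8 had reads in both csf1ra-/- libraries and 0 in both controls. Microglia identity genes had a median log2 difference of 0.00 over 39 members (camera adjusted p = 0.918), with 20 members above 0.

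In compound mutants against control, 234 genes passed by limma, 169 higher and 65 lower, and in all 234 both libraries of one group lay above both of the other. Such separation held for 58.6% of tested genes, where chance gives 1 in 3. At an unadjusted limma p under 0.05 the split leaned the other way, with 2536 genes higher and 3319 lower. In simulated data limma recovered 31 of 33 genes raised 16-fold and 17 of 34 lowered 16-fold. The excess of rises among the calls may thus come from the test. Of the 234 genes, those that rose include 5 of 34 genes of antigen presentation, 3 of 41 of lysosomes, 7 of 49 of chemokine signaling and 3 of 20 oligodendrocyte markers. With an estimated correlation none of these lists was called by camera (adjusted p = 0.518, adjusted p = 0.518, adjusted p = 0.207 and adjusted p = 0.518). With clone-style names left out, the largest rises among genes with a symbol were kcnk18, a potassium channel, from 0.562 ± 0.602 to 321 ± 270 units of signal (SD, n = 2; log2 fold change 7.43 ± 0.77 SE). It was followed by serpine2, a protease inhibitor (5.79), csrp1b (5.67), epdl1 (5.59 ± 0.49, from 31.6 to 1590), and glulb, a glutamine synthetase (5.51 ± 0.60). Next came pla1a (5.41), ggh (5.33), sftpbb (5.21), the chemokine gene ccl34b.8, with 0 reads in both controls and at least 168-fold higher, and the MHC class I gene mhc1uka (5.00). The largest falls, again without clone-style names, some of which fell further, were those of nptna, a cell adhesion protein of neurons (-7.35 ± 0.75, from 250 to 0.317), and sh3d19, with 0 reads in both compound mutant libraries and at least 534-fold lower. Then came the activin subunit inhbb (-5.67), the sodium channel subunit scn4bb (-5.04) and samd4a (-5.00). They were followed by adgrb1b (-4.78), U2 (-4.76), myhz2, a muscle myosin (-4.69), and the matrix genes hspg2 (-4.67) and tnc (-4.64). The U2 value is uncertain, since 12 genes of this symbol were tested and 5 of them passed, and reads could be split among them. Bounds are against a floor of 3 reads over the group, and cover counting error only.

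Antigen processing and presentation had 5 members that rose and 0 that fell of 34 tested, and 12 and 1 adjusted over the list alone. Its median log2 difference was 1.31 (camera adjusted p = 3.38e-07, and adjusted p = 0.518 with an estimated correlation). Those that rose were 4 MHC class I genes, mhc1uka, mhc1zca (3.90 ± 0.64 SE, n = 2 per group), mhc1zea (3.11 ± 0.57) and mhc1zaa (2.85 ± 0.53), and the cathepsin gene ctss2.1. The 1 lower on the second count was the class I gene mhc1uba, at 1801 in control, 148 in csf1ra-/- and 41.2 in compound mutants (log2 difference -5.44, limma adjusted p = 0.0650 over all genes). These class I genes form a family of similar copies, a second gene of the symbol mhc1zaa had a log2 difference of -0.76, and the reads of single members are uncertain. Haplotype or strain variants, considered below for other genes, were not tested for these copies. They cannot be told apart here from an effect of genotype. Lysosomal proteins and proteases had 3 that rose and 0 that fell of 41, and 8 and 2 adjusted over the list alone, with a median of 1.19 (adjusted p = 1.97e-06 by camera, and adjusted p = 0.518 with an estimated correlation). They were the granulin precursors grn1 (4.09 ± 0.53, from 28.4 to 516) and grn2 (3.53 ± 0.63), and ctss2.1 (2.71 ± 0.51), which both lists hold. The 2 that were lower on the second count were copies under the symbol ctslb. Nuclear-encoded respiratory chain subunits had 3 of 82 that rose, cox6b1 (from 24.3 to 241), cox4i2 (4.12) and cox7a1 (3.46), 0 that fell, and 6 and 0 adjusted over the list alone. Their median was 0.89 (camera adjusted p = 1.31e-07, and adjusted p = 0.604 with an estimated correlation).

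Chemokines and chemoattractant receptors had 7 members that rose and 0 that fell of 49 tested, and 14 and 1 adjusted over the list alone. Their median log2 difference was 0.99 (camera adjusted p = 1.04e-04, and adjusted p = 0.207 with an estimated correlation). Among them were ccl35.2 (3.23 ± 0.49 SE, n = 2 per group, from 67.5 to 640), ccl19a.1, whose mammalian relative guides dendritic cells and T cells (3.79 ± 0.64, from 370 to 5314), the receptor ccr9a (3.96 ± 0.64) and ccl34b.8. The interferon list had 2 that rose, the transcription factor stat1b (3.62 ± 0.54) and the feedback regulator socs1a (3.84 ± 0.68), and 0 that fell of 43, and 4 and 0 adjusted over the list alone. Its median was 1.28 (adjusted p = 3.42e-04 by camera, and adjusted p = 0.207 with an estimated correlation). Inflammatory mediators had 1 that rose, the Toll-like receptor adaptor myd88 (4.02 ± 0.56), and 0 that fell of 41, and 9 and 2 adjusted over the list alone. Their median was 0.88 (camera adjusted p = 0.00387, and adjusted p = 0.544 with an estimated correlation). Integrins, adhesion receptors and leukocyte cytoskeleton regulators had 0 members past the test over all genes of 48, and 11 higher and 1 lower adjusted over the list alone, among them pxna (2.85) and arpc1b (2.88). Their median was 0.43 (adjusted p = 0.00387 by camera, and adjusted p = 0.604 with an estimated correlation). Without control replicate 1, camera gave adjusted p of 0.0958 for the inflammatory and 0.0817 for the integrin and cytoskeleton list.

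Markers of other cells moved with these groups in both directions. The endothelial and neuronal lists had lower medians, but held few members far above the floor. At an average log2 signal of at least 4, 3 endothelial members had a median of -1.31 and 2 neuronal members 0.05. At a cut of 2, 12 and 15 members had -1.06 and -0.75. Background reads in control libraries, considered below, could lower the log2 difference of members near the floor. Oligodendrocyte lineage markers had 3 members that rose and 0 that fell of 20 tested, and 8 and 1 adjusted over the list alone. They were the myelin genes mpz (3.54 ± 0.54 SE, n = 2 per group, from 57.4 to 661) and plp1b (4.72 ± 0.95, from 53.1 to 1475), and the claudin gene cldnk (3.44 ± 0.64). The list's median lay 1.36 above that of all genes (camera adjusted p = 0.00387, and adjusted p = 0.518 with an estimated correlation). Radial glia and ependymal markers had 2 that rose, glulb and s1pr1 (3.69), and 0 that fell of 25, and 3 and 0 adjusted over the list alone. Their median was 0.33 (adjusted p = 0.0172 by camera, and adjusted p = 0.604 with an estimated correlation). B lymphocyte markers had 1 that rose, CD37 (3.61 ± 0.72), 0 that fell of 20, 1 and 0 adjusted over the list alone, and a median of 0.71 (camera adjusted p = 0.0172, and adjusted p = 0.604 with an estimated correlation). Endothelial, mural and meningeal markers had 0 past the test over all genes of 26, 0 higher and 2 lower adjusted over the list alone (col1a1b and vwf). Their median was -1.02, and -1.13 with members at 0 reads set to their bound (adjusted p = 0.00746 by camera, and adjusted p = 0.518 with an estimated correlation). Neuronal markers had 0 past either adjustment of 36, and a median of -0.72, and -0.89 with such members at their bound (camera adjusted p = 0.0363, and adjusted p = 0.604 with an estimated correlation). The radial glia list was at 0.170 without control replicate 1 and 0.191 without compound mutant replicate 2. The B lymphocyte list was at 0.434 and 0.0614 without the same libraries, and the neuronal list at 0.0716 without control replicate 2 and 0.816 without compound mutant replicate 1.

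Microglia and macrophage identity genes had 2 of 39 members that rose in compound mutants against control, the calcium-binding protein gene aif1l (3.52 ± 0.62 SE, n = 2 per group) and cd83 (4.51 ± 0.87), and 0 that fell. Adjusted over the list alone 5 were higher and 1 lower, the latter being the transporter slco2b1 (-2.63). Their median was 0.01, with 20 members above 0 and a camera adjusted p of 0.278. The transcript of mpeg1.1, which gives the reporter line its name and was chosen after its values were seen, stood at 2782 against 912 units of signal (limma adjusted p = 0.112). Immediate early and heat shock genes had 0 past the test over all genes of 57, 5 higher adjusted over the list alone, among them junba (2.77). Their median was 0.83 (camera adjusted p = 0.00387, and adjusted p = 0.604 with an estimated correlation, and 0.288 without compound mutant replicate 1). Growth factor and iron genes had 0 that rose and 1 that fell of 23, pdgfba (-2.98 ± 0.58, from 442 to 57.1), and 3 and 2 adjusted over the list alone, and their camera adjusted p was 0.865. Genes of the mitochondrial genome had 0 past the test over all genes of 13, 1 higher adjusted over the list alone (mt-nd4l). Their median was 0.87 (camera adjusted p = 0.00768, and adjusted p = 0.648 with an estimated correlation, and 0.491 without control replicate 1). Cytosolic ribosomal proteins had 0 past either adjustment of 78 and a median of 0.35 (adjusted p = 0.00720 by camera, and adjusted p = 0.768 with an estimated correlation). On total reads their camera direction turned without a call (camera adjusted p = 0.771). Their median there was -0.36, still above that of all genes, at -0.70.

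Camera called none of the remaining 6 lists in compound mutants against control. Their members past the limma test over all genes were 0 in each list. Adjusted over the list alone, cholesterol and lipid genes had 1 higher and 5 lower of 44 (median -0.39, camera adjusted p = 0.368), and red cell and thrombocyte markers 1 and 1 of 11 (median -1.41 with a mean of -0.02, adjusted p = 0.552). T and natural killer markers had 2 and 2 of 24 (-0.53, adjusted p = 0.451) and neutrophil markers 0 and 1 of 12 (1.01, adjusted p = 0.357). Genes of cell proliferation had 0 past either adjustment of 58 (-0.46, adjusted p = 0.738), and epithelial and metaphocyte markers 0 of 20 (-0.15, and -0.30 with members at 0 reads at their bound, adjusted p = 0.812). Those lower among lipid genes by the list-alone adjustment included the fatty acid binding protein gene fabp11a (-2.82) and the cholesterol synthesis gene hmgcrb (-3.22), and among T cell genes the kinase zap70 (-3.13). For the epithelial and the growth factor lists the median and the camera test differed in sign. The proliferation marker pcna stood at 87.2 and 182 in compound mutants and 15.4 and 19.1 in control (limma adjusted p = 0.0597).

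**Figure D3:**
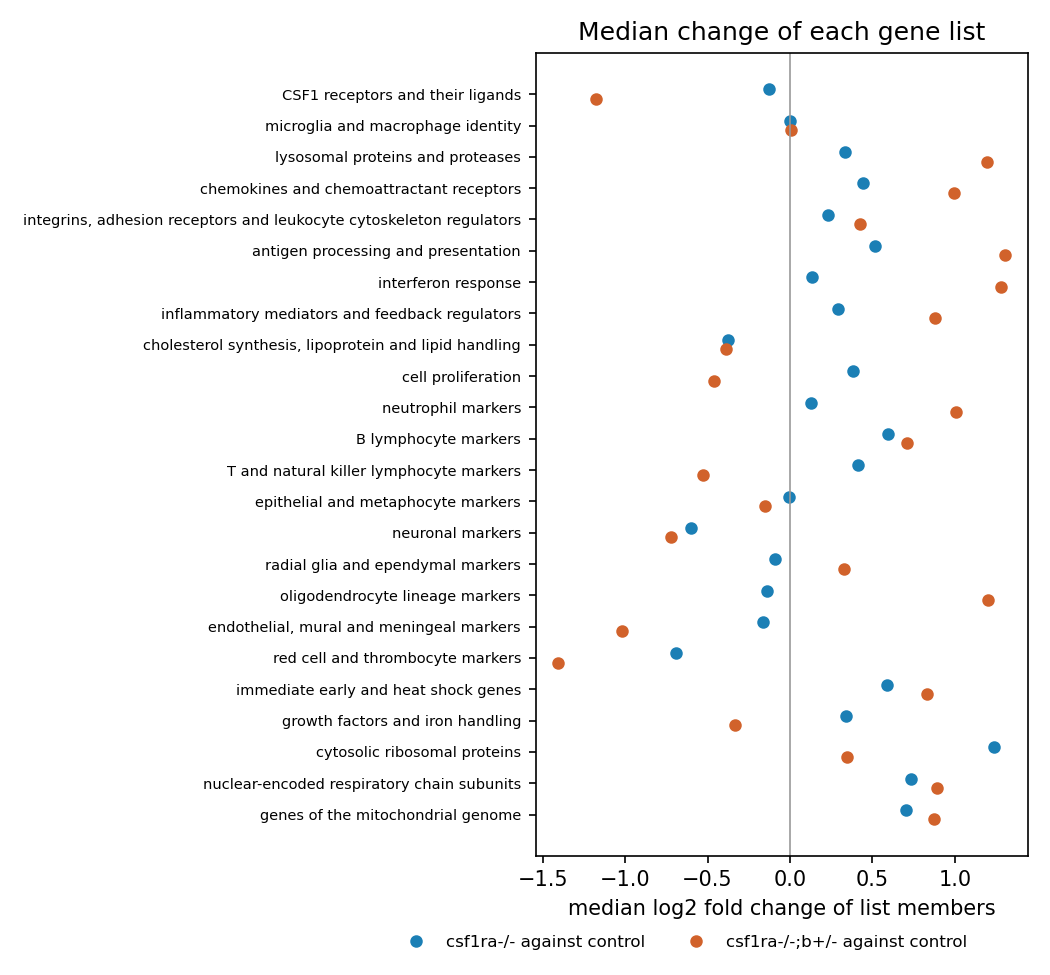
Median log2 fold change of the members of each of the 24 gene lists, in csf1ra-/- against control and in compound mutants (csf1ra-/-;b+/-) against control, with the line at 0. The antigen presentation, lysosome and interferon medians lie above 1 in compound mutants, at 1.31, 1.19 and 1.28 (0.60, 0.48 and 0.57 on total reads). The ribosomal median is 1.24 in csf1ra-/- and 0.35 in compound mutants. On total reads it is -0.36 in the latter, where the median of all genes is -0.70.

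**Figure D4:**
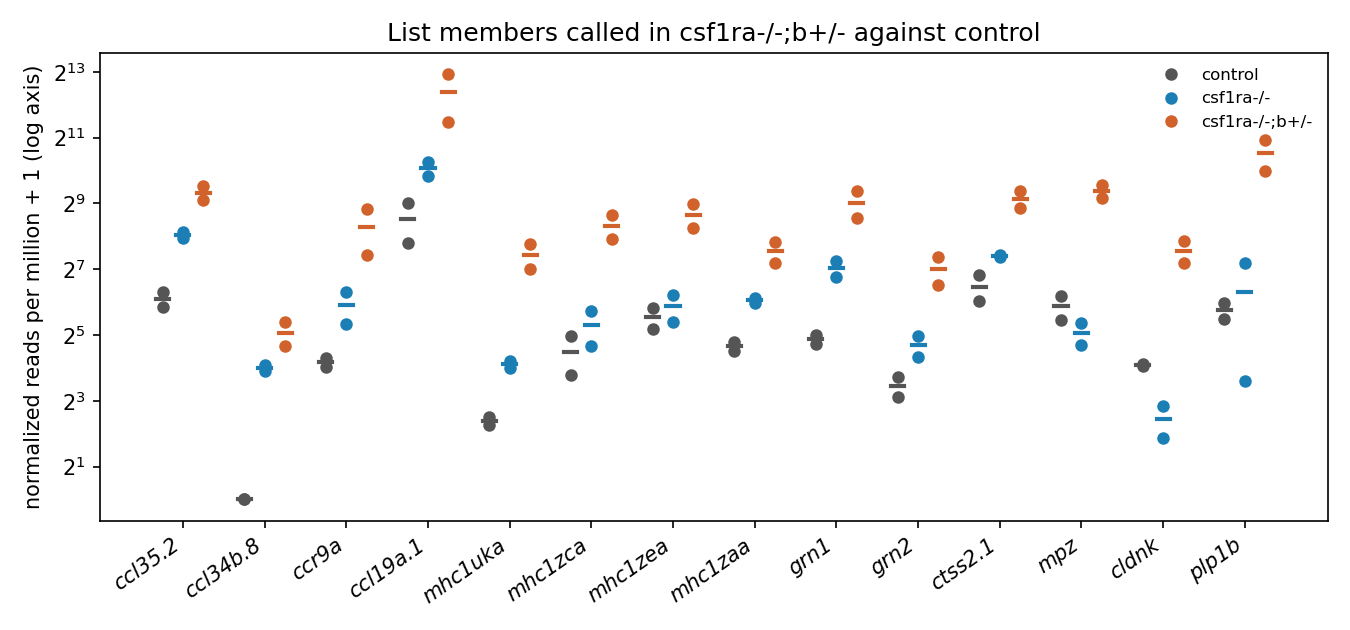
Signal (normalized CPM) plus 1 on a log axis for the called members of the chemokine, antigen presentation, lysosome and oligodendrocyte lists, at most 4 per list, in each library, with circles for libraries, a short line for the mean of a group, and colors for the groups. For each gene shown, both compound mutant libraries lie above both controls, and ccl34b.8 had 0 reads in both controls.

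The count of 234 genes in compound mutants against control changed with each library left out. It was 0 without control replicate 1, 0 without csf1ra-/- replicate 1, 0 without csf1ra-/- replicate 2, 117 without control replicate 2, 84 without compound mutant replicate 1 and 19 without compound mutant replicate 2, and 0 when only the 4 libraries compared were fitted. The 20 genes named above for the largest changes were picked among genes that did not overlap between groups. Their sign thus could not change in these fits, and its constancy is no evidence of stability. Fewer of them passed without a single library. On recovered reads edgeR called 353 genes (205 higher, 148 lower), 212 of them among the 234, and DESeq2 called 3696 (1184 and 2512). The authors' deposited table holds 4601 genes under a false discovery rate of 0.05, 1420 higher and 3181 lower, and all 234 genes are among them with the same sign. The split of calls also moved with the scaling. It was 169 higher and 65 lower with the authors' scaling, 92 and 126 on total reads, and 128 and 70 with median-ratio factors. The median log2 difference of all genes was -0.16, -0.70 and -0.33 in the same order, and the list medians, not taken relative to it, were 0.48 on total reads and 0.97 with median-ratio factors for lysosomes and 0.63 and 1.02 for oligodendrocyte markers. Camera called 9 lists without control replicate 1. Of the 15 lists called, 7 were called in each of 11 alternative settings, namely lysosomes, chemokines, antigen presentation, interferon, the respiratory chain, oligodendrocyte and endothelial markers. These settings leave out the estimated correlation, with which 0 lists were called, and fry, which called 1.

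By genotype, compound mutants differ from csf1ra-/- in 1 csf1rb copy. Their libraries were also deeper, at 15011963 and 13543998 reads against 8028386 and 7874979, so the comparison cannot isolate that copy. In compound mutants against csf1ra-/-, 5 genes passed by limma, 2 higher and 3 lower. The 2 that rose were the oligodendrocyte markers cldnk, from 4.43 ± 2.50 to 187 ± 58.4 units of signal (SD, n = 2; log2 fold change 5.16 ± 0.64 SE), and mpz, from 32.4 ± 10.8 to 661 ± 124 (4.34 ± 0.54), both with a limma adjusted p of 0.0425. Those that fell were the clone-named gene ENSDARG00000104635, at 305 ± 243 in csf1ra-/-, si:busm1-48c11.3, at 153 ± 73.7, and CABZ01113061.1, at 72.6 ± 43.5. The first and second of these had 0 reads in both compound mutant libraries, and were at least 2362-fold and 1187-fold lower, and the third had 2 reads. These 3 were named after their values were seen. Oligodendrocyte markers had 2 members that rose and 0 that fell of 20, and 7 and 0 adjusted over the list alone, with a median log2 difference of 0.35 (camera adjusted p = 0.00413, and adjusted p = 0.475 with an estimated correlation).

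Among the other lists, 0 members passed over all genes in compound mutants against csf1ra-/-, and 9 lists were called by camera, and 0 with an estimated correlation. Lysosomal genes had a median of 0.88 with 36 of 41 members above 0 (adjusted p = 1.70e-06, and adjusted p = 0.475 with an estimated correlation), among them tpp1 (2.17 ± 0.56 SE, n = 2 per group) and grn1 (1.95 ± 0.53). Antigen presentation had a median of 0.80 with 29 of 34 above 0 (adjusted p = 4.41e-07 by camera, and adjusted p = 0.475 with an estimated correlation), and 3 members higher adjusted over the list alone, mhc1uka, mhc1zea and mhc1zca. The interferon list had a median of 0.75 (adjusted p = 1.30e-04 by camera, and adjusted p = 0.345 with an estimated correlation). The chemokine list had 0.68 (adjusted p = 0.00451, and adjusted p = 0.371 with an estimated correlation), with s1pr1 higher adjusted over the list alone. Adhesion and cytoskeleton genes had 5 members higher adjusted over the list alone, among them cd9b (5.58), pxna and cd44b, and a camera adjusted p of 0.00451, with adjusted p = 0.533 with an estimated correlation. The inflammatory list (median 0.57) and radial glia markers (0.57) both had a camera adjusted p of 0.00359 and adjusted p = 0.475 with an estimated correlation, and 2 radial glia markers were higher adjusted over the list alone, glulb and s1pr1. Cytosolic ribosomal proteins had 7 of 78 members above 0 and a median of -0.89 (camera adjusted p = 1.94e-07, and adjusted p = 0.649 with an estimated correlation). Endothelial markers had a median of -1.15, and -1.16 with members at 0 reads at their bound (adjusted p = 0.00440 by camera, and adjusted p = 0.429 with an estimated correlation).

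The radial glia call of compound mutants against csf1ra-/- ended without compound mutant replicate 2 (adjusted p = 0.0999), and the ribosomal and endothelial calls without csf1ra-/- replicate 2 (0.217 and 0.0643). The count of 5 genes was 0 without either control or either csf1ra-/- library, 3 without compound mutant replicate 1 (0 higher, 3 lower), 5 without compound mutant replicate 2 (0 higher, 5 lower), and 0 when only the 4 libraries compared were fitted. Thus cldnk and mpz lost their call with any 1 library left out. On total reads it was 25, 15 higher and 10 lower, and with median-ratio factors 7, 2 higher and 5 lower. The median log2 difference of all genes was -0.17 with the authors' scaling and -0.30 on total reads. In this comparison 2760 genes had an unadjusted limma p under 0.05, and edgeR called 14, DESeq2 1471, and the authors' deposited list holds 1673 (435 higher, 1238 lower).

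Taking the mean of both mutant groups against control, 43 genes passed by limma, 33 higher and 10 lower. The largest rises, without clone-style names, were in kcnk18 (log2 fold change 5.72 ± 0.67 SE), epdl1 (4.73 ± 0.43), sftpbb (4.66 ± 0.54) and sftpba (4.60 ± 0.51). The last stood at 7.93 ± 2.94 units of signal in control, 212 ± 112 in csf1ra-/- and 227 ± 48.7 in compound mutants (SD, n = 2). Then came the retinol-binding protein gene rbp2a (4.58), ccl34b.8, at least 123-fold higher, ggh (4.49), smfn (4.38), phlda2 (4.33) and mrpl51 (4.31). The named falls were sh3d19 (-5.54), nptna (-4.66), scn4bb (-4.12) and ZFOS-741A10.4. The last, a clone-style name that the patterns of the rule did not exclude, had 0 reads in all mutant libraries and was at least 171-fold lower. By list, 2 chemokine genes rose (ccl34b.8 and ccl35.2), and 1 each of the lysosomal (grn1), antigen presentation (mhc1uka), inflammatory (myd88) and radial glia (glulb) lists, and 0 members of any list fell. Adjusted over the list alone, the counts higher and lower were 11 and 0 for chemokines, 4 and 0 for lysosomes and 9 and 1 for antigen presentation. Camera called 13 of 23 lists, among them lysosomes (median 0.75, adjusted p = 1.21e-04), chemokines (0.90, 1.63e-04) and antigen presentation (0.93, 7.51e-06), the 3 that were called in each of 11 alternative settings. Those leave out fry, which called 1 list, and the estimated correlation, with which 0 were called and these 3 were at adjusted p = 0.531, adjusted p = 0.348 and adjusted p = 0.531.

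The remaining 10 lists called for both mutant groups against control were ribosomal proteins (median 0.80) and the respiratory chain (0.77), both at a camera adjusted p of 3.17e-10, immediate early genes (0.75, adjusted p = 0.00275) and the mitochondrial genome (0.80, adjusted p = 0.00302). With an estimated correlation these 4 were at adjusted p = 0.531, as were the 6 that follow but for interferon, at adjusted p = 0.394. They also include interferon (0.53, adjusted p = 0.00545), B lymphocyte markers (0.64, adjusted p = 0.00778) and adhesion and cytoskeleton genes (0.44, adjusted p = 0.0126). The last were inflammatory mediators (0.62, adjusted p = 0.0156), oligodendrocyte markers (0.79, adjusted p = 0.0218) and neuronal markers (-0.59, adjusted p = 0.0322). Camera called 3 lists without control replicate 1 and 8 without csf1ra-/- replicate 1. On total reads the median of all genes moved from -0.10 to -0.56, and relative to it the interferon median was 0.54 against 0.63 with the authors' scaling. The count of 43 genes was 0 without control replicate 1, 1 without control replicate 2, 0 without either csf1ra-/- library, and 65 without compound mutant replicate 1. With the authors' scaling the split was 33 higher and 10 lower, and on total reads 25 and 27. Here 4381 genes had an unadjusted limma p under 0.05, and edgeR called 64 (32 higher, 32 lower), DESeq2 1770 (721 and 1049), and the authors' deposited list holds 2779 (773 and 2006).

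Both mutant groups were compared with the same controls, so their changes share chance values. Across genes, the log2 differences of csf1ra-/- and of compound mutants from control correlated at 0.623, against 0.499 in simulated unchanged groups, and had the same sign in 71.8% of genes against 66.7%. Their covariance was 1.06 against a simulated 0.356, a difference of 0.704. Of the 234 genes called in compound mutants, 213 had the same sign in csf1ra-/-, among them epdl1 (3.87 in csf1ra-/- against 5.59) and kcnk18 (4.00 against 7.43). That is 91.0%, below the 94.7% among as many top genes of simulated unchanged groups, since genes picked with the same controls tend to share a sign. By limma 0 genes were called in both groups, since 0 were called in csf1ra-/-, where 2242 had an unadjusted p under 0.05. By edgeR all 8 genes called in csf1ra-/- were also called in compound mutants in the same direction, where independent lists would share 0.0487 higher and 0.0211 lower genes and simulated unchanged groups shared 0. The value for independent lists leaves out the shared controls, and unchanged groups hold hardly any calls to share, so neither is a no-change value for this overlap. DESeq2 called 196 genes in both. With 2 controls, separate sets of 2 could not be formed for each mutant group, so part of the excess may come from the shared controls.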

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

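The tests of depth, background reads and all 3 tests on oligodendrocyte transcripts were chosen only after the result was seen, and those of scaling and of loss of microglia were changed 2 times after earlier versions had been run. The direct contrast between the mutant groups tests whether their differences from control differ, and in it 5 genes and, by camera, 10 lists passed, and 0 lists with an estimated correlation (adjusted p from 0.345 to 0.649). The genes were cldnk (log2 fold change 5.16), mpz (4.34), CABZ01113061.1 (-5.94), si:busm1-48c11.3 (-7.18) and ENSDARG00000104635 (-7.99). The last 2 had 0 reads in both compound mutant libraries, so their fitted values are no bound. The lists, with camera adjusted p, were lysosomes (1.70e-06), chemokines (0.00451), integrins and cytoskeleton (0.00451), antigen presentation (4.41e-07), interferon (0.000130), inflammatory mediators (0.00359), radial glia (0.00359) and oligodendrocyte markers (0.00413), all higher in compound mutants, and endothelial markers (0.00440) and ribosomal proteins (1.94e-07), lower, and with an estimated correlation these are the 10 lists at adjusted p from 0.345 to 0.649.

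Of 20 oligodendrocyte markers, 3 passed as higher in compound mutants against control and 2 against csf1ra-/-, with 0 lower, and with an estimated correlation the list was at adjusted p = 0.518 and adjusted p = 0.475 by camera. Library scaling was tested on total reads. There the 14 members with an average log2 signal of at least 2 kept a median of 1.53 against control (bootstrap 95% interval over members 0.601 to 2.59). That average includes the compound mutant libraries, so a rise there helps a member to pass it. Over all 20 members the median was 0.63 (-0.801 to 1.59), so scaling is not excluded for the list as a whole. The calls of plp1b (4.72 ± 0.95 SE to 4.01 ± 0.93) and cldnk (3.44 ± 0.64 to 2.74 ± 0.69) ended as their differences shrank. The call of mpz was kept on total reads (3.54 ± 0.54 to 2.83 ± 0.45, limma adjusted p = 0.0138). Loss of microglia from the sorted cells was tested on the premise that it would raise markers of every other cell alike. Over all members the oligodendrocyte median lay 2.22 above the vascular one (interval widened for 3 cell types, 0.347 to 3.73). The vascular median was itself below 0 (-1.02). Clear of the floor, at an average log2 signal of at least 2, the oligodendrocyte median lay 3.29 above the vascular one (1.86 to 4.87). Radial glia markers did not part from oligodendrocyte markers (0.87, -1.80 to 2.60). Background reads in control libraries could lower the log2 difference of vascular markers near the floor. Only 3 vascular members had an average log2 signal of at least 4. The values thus argue only against an equal rise of all other cells, and less so if background reads played a part. They cannot exclude loss of microglia from a sort that holds some other cells and not others. The intervals also span list members, not libraries. Oligodendrocytes or their RNA carried through the GFP sort may be a source, and cannot be told apart from a change in the sorted cells. Of 8 members with a mean signal of at least 20, 50% had a log2 difference above 1 against csf1ra-/- (plp1b, cldnk, mpz and mbpa) and mbpb, fa2h, tspan2a and cnp did not (0.61, 0.12, -0.32 and -1.01), between the shares set for and against, while 7 lay above 1 against control, all but cnp (-0.17).

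A set of 7 genes was near 0 in the libraries of 1 or 2 groups and well expressed elsewhere, among them CU929449.2, si:dkey-18p12.4 and si:busm1-48c11.3, chosen after their values were seen. Chance between single libraries is argued against, since 0 such genes arose in any split of 2 against 4 libraries that did not follow genotype, against 4 in the largest of the genotype splits. Chance differences between fish or pools cannot be excluded, since the libraries of a group may come from the same ones. Linked haplotype or strain variants may explain them and cannot be told apart from an effect of genotype, because only 14.3% of the genes could be matched to the GRCz12tu annotation for a test of neighbours.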

How the results depend on the processing

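Pseudocounts and scaling to total reads were chosen only after the data were seen, as was limma in place of the planned edgeR test. Genes called in csf1ra-/- against control (0 by limma, 2242 at an unadjusted p under 0.05) were 8 by edgeR with and without robust estimation, 264 by DESeq2, 5 with RLE scaling and 5 on total reads, 13 with at least 50 reads, 2 with a pseudocount of 4, 6 with only the 4 libraries compared, and 0 to 6 leaving out each library. For compound mutants against control (234) they were 353 by edgeR, 3696 by DESeq2, 947 with at least 50 reads, 108 with a pseudocount of 0.25, 0 with only the 4 libraries compared, and 0 to 117 leaving out each library. For compound mutants against csf1ra-/- (5) they were 14 by edgeR with and without robust estimation, 1471 by DESeq2, 25 on total reads, 50 with at least 50 reads, 3 with a pseudocount of 0.25, 0 with only the 4 libraries compared, and 0 to 5 leaving out each library. For both mutant groups (43) they were 1770 by DESeq2, 247 with at least 50 reads, 25 with a pseudocount of 4, 13 with mutant libraries pooled, and 0 to 65 leaving out each library. With the title number as a replicate block the counts were 12, 543, 36 and 155 and the overlap 12. However, deviations of same-numbered libraries from their group means correlated between groups at only 0.00600, 0.0180 and 0.0122, so the numbers show no pairing. The overlap of both mutant groups (0 by limma) was 8 by edgeR with and without robust estimation, 196 by DESeq2, 5 with RLE scaling, 5 on total reads, 13 with at least 50 reads, 2 with a pseudocount of 4, and 0 to 5 leaving out each library. DESeq2 made 153 false calls of 291 in the simulation. With an estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 1 in each. The chemokine and interferon lists lost their calls too, at estimated correlations of -0.0156 and -0.00256, below the preset 0.01. For these lists the loss thus does not come from correlation among members. Nor does a lost call show such correlation for the other lists, since 6 libraries in 3 groups leave few degrees of freedom. Against control, fry called the chemokine list in csf1ra-/- (fry adjusted p = 0.00771) and in compound mutants (fry adjusted p = 0.00283). Lists called by camera leaving out each library were 1 to 10 for csf1ra-/- (7), 9 to 15 for compound mutants (15), 8 to 12 between mutants (10) and 3 to 14 for both (13). Direction turned for immediate early genes in csf1ra-/- (adjusted p from 1.63e-05 to 0.953 leaving out each library, the latter without csf1ra-/- replicate 1) and for ribosomal proteins in compound mutants (0.771 on total reads, and from 9.04e-09 to 0.316 leaving out each library, the latter without control replicate 1). Leaving out a library assumes that the lone library of its group varies like the others. With no filter the counts were 0, 223, 5 and 34. Of the 20 genes named for the largest changes in compound mutants against control, edgeR called 18, DESeq2 19, RLE scaling 20 and total reads 19. The cause was not tested for these shifts. The shallowest library held 4241988 reads, and 1 read was worth 0.0809 to 0.157 units of signal depending on the library.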

Other observations

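The test of depth and the test of background reads were chosen only after the result was seen. Members of the microglia identity list, picked out after their values were seen, differed from each other in pattern. Signal of mpeg1.1 was 912 in control, 631 in csf1ra-/- and 2782 in compound mutants, while apoeb stood at 7787, 3030 and 7089 and p2ry12 at 29.5, 29.9 and 14.3, and none of the 3 passed limma in compound mutants against control. Reads on the transcript AC024175.4 made up 11.5% and 10.8% of the control libraries, 16.1% and 14.6% of csf1ra-/- and 15.7% and 12.9% of compound mutants.

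More genes had reads in control than in compound mutant libraries. Sequencing depth is argued against, since with all libraries thinned to the smallest total the lower control still had 3540 more genes than the higher compound mutant library, beyond the 1210 between the controls. Background reads spread over the genome in control libraries may contribute, since of 154 genes of odorant and taste receptors, crystallins, egg coat proteins and similar families, 89.6% had reads in both controls, 72.1% in both csf1ra-/- and 27.3% in both compound mutant libraries. Among all other genes these shares were 91.3%, 84.3% and 66.8%, and the table holds only genes with reads in at least 2 libraries. Molecules lost in the compound mutant libraries cannot be told apart from background reads in the controls. Of genes with at least 20 reads in 1 replicate, 5.27% had 0 in the other, against 3.64% in control and 3.62% in csf1ra-/-, short of the 1.5 times set beforehand.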
